A study of Jaltomata procumbens and Jaltomata herrerae with 23 samples.

How the data were processed

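RNA-seq libraries from floral nectaries and leaves of Jaltomata herrerae and Jaltomata procumbens were analysed. Per the labels' protocols, nectaries were dissected by hand before secretion (24 to 48 h before anthesis), during it (full anthesis, 3 to 6 h after dawn) and after petal abscission, and leaves were fully expanded. Per the labels, libraries were TruSeq stranded mRNA, sequenced as 150 bp paired-end reads on a NovaSeq at a mean depth of at least 20 M reads. Quantification used kallisto 0.46.1, per the submitters' processing notes. The deposited score is TPM, rounded to whole numbers by the authors, for 13170 Arabidopsis loci. The reference, the matching of Jaltomata transcripts to Arabidopsis loci and their aggregation are not given in the sources used here.

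Samples were grouped by their labels into 8 groups: herrerae pre-secretory (3 libraries), secretory (3) and post-secretory nectary (3) and leaf (2), and procumbens pre-secretory (4), secretory (2) and post-secretory nectary (3) and leaf (3). The labels plan 24 libraries and 23 were analysed here. They do not say that replicates are separate plants, so p-values measure only the spread between these samples. TPM keeps no read depth, so the precision of a low value cannot be given per library. Each library had 11331 to 12449 loci at 1 TPM or more and a listed total of 542947 to 779099 TPM.

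Loci with at least 1 TPM in at least 2 libraries were kept (13080 of the 13170). Among the others, 77 were at 0 in every library. Values were tested as log2(TPM + 1) in limma 3.58.1 on R 4.3.3, with 1 mean per group, a trend in the prior variance and Benjamini-Hochberg adjustment per comparison, and a locus was called at an adjusted p under 0.05. Each locus had 1 variance over all groups, so SEs and p-values within herrerae also carry the spread of the procumbens libraries, and the reverse. The 13 comparisons were secretory against pre-secretory, post-secretory against secretory and all nectary stages against leaf in each species, herrerae against procumbens in each of the 4 tissues, and the differences between species in the 3 within-species comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures. The steps were tested on simulated data: for herrerae secretory against pre-secretory 38% of 100 loci changed 2-fold and 88% of 100 changed 4-fold were recovered with 11 calls among unchanged loci, and for procumbens 16% and 90% with 12. The simulated spread was taken without the 3 procumbens libraries named below, and the changed loci left out the lowest ones. These shares thus do not describe the recovery with the spread of all 23 libraries.

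Before the data were examined, 30 gene lists, the comparisons, the tests and the first set of alternatives were chosen. Of the lists, 22 had Arabidopsis loci (173 loci, 147 in the table): sucrose synthesis and export, starch synthesis, starch breakdown, carbonic anhydrase, berberine bridge enzyme-like, monolignol, proline, flavonoid, carotenoid, nectary development, jasmonate, auxin, ethylene, senescence, pumps and aquaporins, cell cycle, photosynthesis, pollen and anther, carpel and ovule, vascular, trichome and petal. The other 8 were text searches and could not be used, since the table gives loci without names. Gene symbols come from the lists. Lists with at least 5 tested members (16) were tested with camera in limma, 208 pairs of list and comparison in all. Each pair was tested at a preset correlation of 0.01 and at an estimated one, adjusted over the lists of a comparison. Called members were counted over all loci and adjusted over the list alone.

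Genes were named by a rule: the highest and lowest called loci without overlap between groups, with at most 2 locus identifiers each way where no name is known, and up to 3 called members of each list with a camera call or at least 3 called members. SWEET9, CWINV4, SPS1F, BCA1, AT4G20860, CRC, MYB21 and MYB24 were always named, and a gene named in 1 comparison was followed in others. The same rule was applied to the fit on 20 libraries, after the data were seen.

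Alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5 (10351 loci), rescaling by median ratios over the 9497 loci above 0 in every library, a replicate block by letter, a fit on the compared groups alone, and leaving out each library in turn. Added after seeing the data were leaving out 3 procumbens libraries (pre-secretory A, post-secretory A and leaf A, which correlated better with another group), alone, with rescaling (20 libraries, 13075 loci) or with loci detected in both species, and removing 3 dominant loci. These loci were the highest over the herrerae nectary libraries, and the rest was rescaled to a common total. Removing them thus raises other herrerae nectary values against leaf and procumbens by construction. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. Results on the deposited values with all 23 libraries come first in each comparison.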

Results

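Floral nectaries of Jaltomata herrerae and Jaltomata procumbens were compared before, during and after nectar secretion, and with leaves, in 23 libraries of 2 to 4 per group. Most libraries correlated best with the other libraries of their labelled group, and 4 procumbens libraries did not. Pre-secretory A reached r = 0.46 with its own group and 0.893 with herrerae leaf. Post-secretory A reached 0.833 against 0.981 with procumbens secretory nectary, and leaf A 0.711 against 0.97 with procumbens post-secretory nectary. The leaf genes followed: RBCS1A, which encodes a small subunit of Rubisco, stood at 33316 TPM in pre-secretory A against 27 to 70 in the other 3 pre-secretory libraries. It stood at 61 in leaf A against 26660 and 40642 in leaf C and leaf B. Procumbens pre-secretory C lay nearer the secretory group (r = 0.959) than its own (0.913), by the smallest margin of the 4. It was kept in every setting except where each library was left out in turn, a choice made after these values were seen. Every library stays in the group its label gives. Each comparison is also given without pre-secretory A, post-secretory A and leaf A and with median ratio rescaling (20 libraries, 13075 loci). That setting was chosen after the data were seen and is called the 20-library fit below. Its libraries are all part of the full set. Calls shared with the full set in the same direction are thus no independent support.

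**Figure D1:**
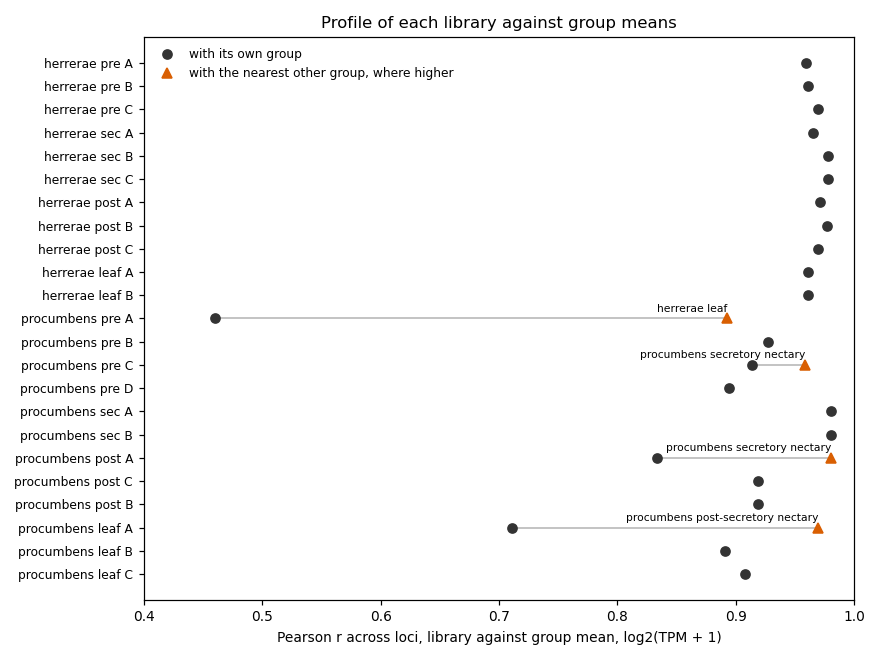
Pearson r of the log2(TPM + 1) profile of each library with the mean of the other libraries of its labelled group (circles) and, where higher, with the nearest other group (triangles). Procumbens pre-secretory A (0.46 against 0.893), post-secretory A (0.833 against 0.981) and leaf A (0.711 against 0.97) lie nearer another group, as pre-secretory C does by less (0.913 against 0.959).

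A set of 3 loci held much of the listed signal in herrerae nectaries: AT5G50290, AT5G36210 and AT2G01021 together made up 30.6 ± 18.4% before, 37 ± 10.2% during and 19.4 ± 5.45% after secretion (mean ± SD, n = 3 each). They made up 4.76 and 6.79% in the 2 herrerae leaf libraries. In procumbens they made up 0.809 to 6.48% of the listed TPM. These loci were singled out after their values were seen. Rescaling by median ratios brings medians near 0 by construction, so the moves below give the size of a shift and not its cause. The median log2 change of all loci moved from -0.39 to -0.04 for secretory against pre-secretory herrerae nectary, and from 0.86 to 0.14 for post-secretory against secretory. It moved from 0.22 to 0.03 and from 0.17 to -0.03 for the procumbens post-secretory and nectary against leaf comparisons. For herrerae against procumbens it moved from -0.59, -0.84, -0.28 and -0.38 to -0.06, 0, 0.05 and 0.05 in pre-secretory, secretory and post-secretory nectary and in leaf. For the differences between the species in stage or tissue change it moved from -0.27, 0.61 and -0.18 to 0.03, 0.08 and -0.04 (secretory, post-secretory, nectary against leaf).

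**Figure D2:**
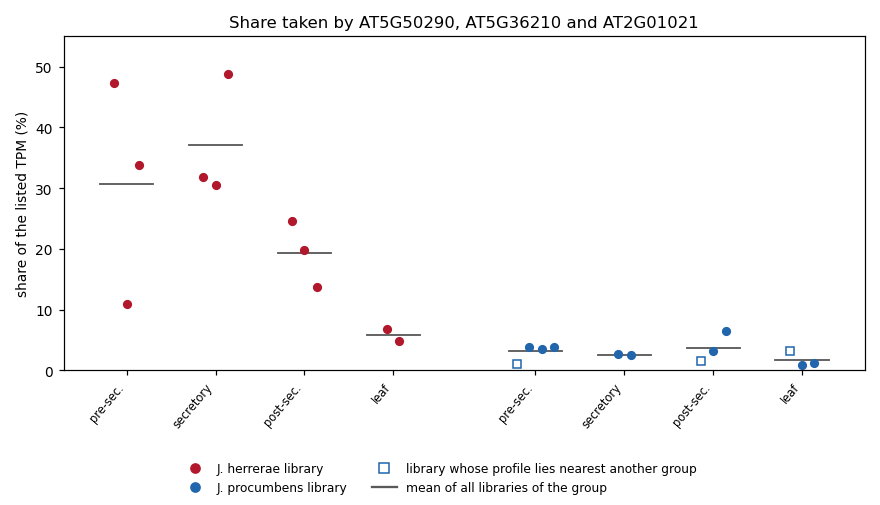
Share of the listed TPM (%) held by AT5G50290, AT5G36210 and AT2G01021 together in each library, by group (red, J. herrerae; blue, J. procumbens; open squares, the 3 libraries absent from the 20-library fit; lines, group means). The share averaged 37% in herrerae secretory nectaries and lay between 0.809 and 6.48% in procumbens.

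Values in brackets are log2 changes unless a unit is given, and list counts are over all loci first. In herrerae, the start of secretion came with more transcript for a carotenoid enzyme and a water channel (n = 3 and 3). PSY, the first committed enzyme of carotenoid synthesis, rose by 3.97 (SE 0.7, adjusted p = 0.00601) on the log2 scale, from 32 ± 12.1 to 503 ± 150 TPM. PIP1;3, a plasma membrane aquaporin, rose by 3.07 (SE 0.43, adjusted p = 0.000765), from 47 ± 19.2 to 406 ± 184 TPM. SS2, a starch synthase, fell by 2.62 (SE 0.62, adjusted p = 0.0343, or 0.0513, 0.176 and 0.109 without pre-secretory A, B and C and 0.135, 0.0939 and 0.0956 without secretory A, B and C), from 9 ± 2.65 to 0.667 ± 0.577 TPM. The nectary sucrose exporter SWEET9 (1.09, SE 1.88, adjusted p = 0.816) stood at 5200 ± 2282 and 10330 ± 2004 TPM and did not pass the test. Neither did the nectary transcription factor CRC (2.05, SE 1.9, adjusted p = 0.601), the amylase BAM1 (2.79, SE 0.71, adjusted p = 0.0502) or the cell wall invertase CWINV4 (-0.07, SE 2.28, adjusted p = 1). SPS1F, a sucrose phosphate synthase (-0.21, SE 0.54, adjusted p = 0.897), the flower maturation factors MYB21 (-0.06, SE 1.1, adjusted p = 1) and MYB24 (-0.67, SE 1.7, adjusted p = 0.895), the carbonic anhydrase BCA1 (-0.52, SE 2.01, adjusted p = 0.946) and the berberine bridge enzyme-like AT4G20860 (0.06, SE 1.84, adjusted p = 1) did not pass either. Outside the lists AT2G22540 rose by 6.6 (SE 0.78, adjusted p = 0.000223), AT1G52690 rose by 5.98 (SE 0.5, adjusted p = 2.2e-06) and AT5G20150 fell by 4.15 (SE 0.57, adjusted p = 0.000759).

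Of 13080 loci, 227 passed for herrerae secretory against pre-secretory nectary (81 higher, 146 lower, 35.7% higher), and 1161 after rescaling (57.7% higher). The count was 60 and 52 without pre-secretory B and C, and 70, 52 and 55 without secretory A, B and C. With 20 libraries 4381 loci passed (2016 higher, 2365 lower), all 227 among them in the same direction. There CRC rose by 2.51 (SE 0.39, adjusted p = 0.000232), the proline synthesis enzyme P5CR rose by 2.41 (SE 0.33, adjusted p = 0.000101), BAM1 rose by 3.26 (SE 0.48, adjusted p = 0.000173) and the sucrose exporter SWEET11 rose by 1.97 (SE 0.64, adjusted p = 0.0276). Jasmonate synthesis and signalling genes in that fit counted 5 lower of 7, the same adjusted over the list alone, no camera call (adjusted p = 0.0884). The lipoxygenase LOX2 fell by 2.15 (SE 0.43, adjusted p = 0.00152). Photosynthesis genes counted 5 lower of 13, the same adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.78 with an estimated correlation. PSBP1 of photosystem II fell by 2.15 (SE 0.41, adjusted p = 0.00118).

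**Figure D3:**
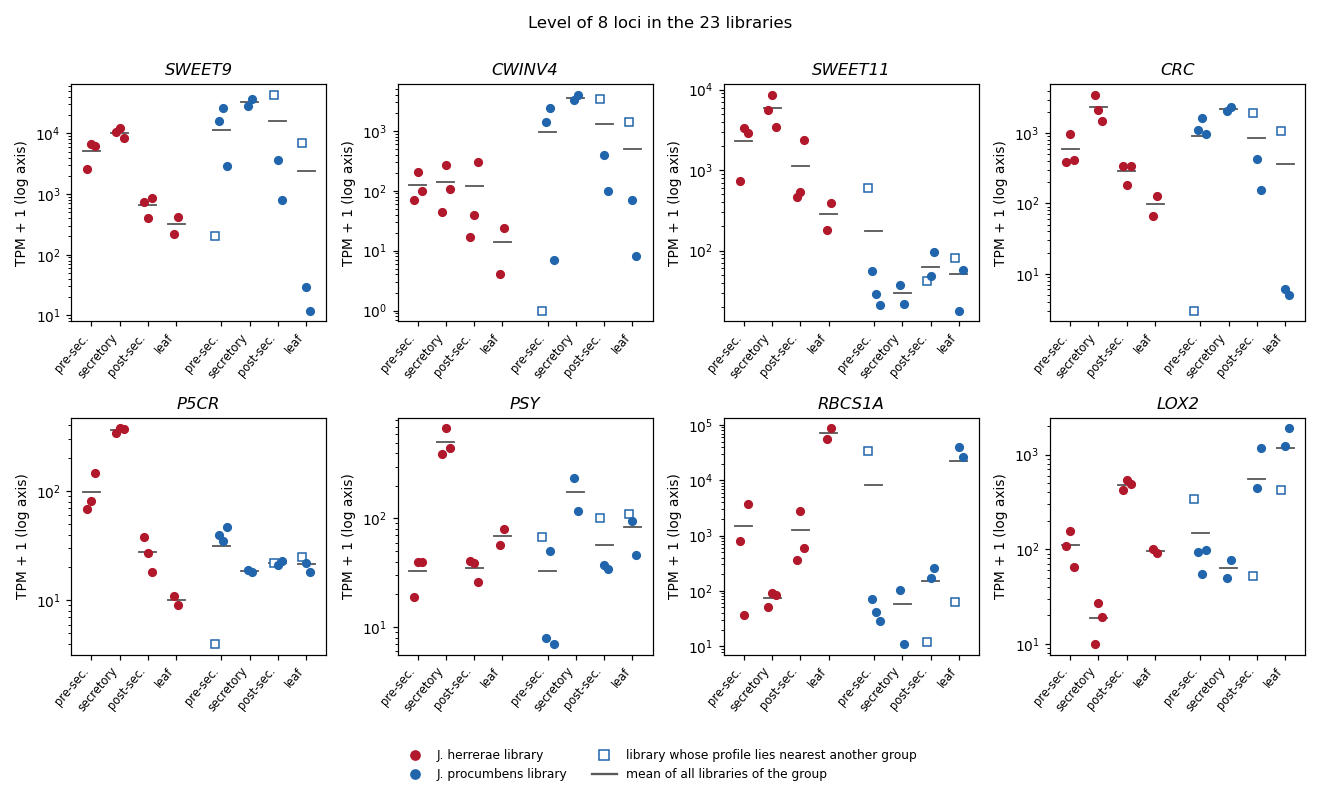
TPM + 1 on a log axis for SWEET9, CWINV4, SWEET11, CRC, P5CR, PSY, RBCS1A and LOX2 in each library, by group (red, J. herrerae; blue, J. procumbens; open squares, the 3 libraries absent from the 20-library fit; lines, means of all libraries of a group). P5CR averaged 361 TPM in herrerae and 17.5 TPM in procumbens secretory nectaries, and SWEET11 5852 and 28.5 TPM.

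In procumbens, none of the listed genes passed for secretory (n = 2) against pre-secretory nectary (n = 4) in limma with all libraries. SWEET9 (3.02, SE 1.99, adjusted p = 0.459) averaged 11330 ± 12030 TPM before and 32480 ± 5565 TPM during secretion. CWINV4 (5.68, SE 2.42, adjusted p = 0.266) stood at 953 ± 1171 and 3600 ± 478 TPM, and AT4G20860 (4.31, SE 1.96, adjusted p = 0.291) at 1741 ± 2486 and 10870 ± 402 TPM. PSY (2.99, SE 0.75, adjusted p = 0.0927, or 0.00865 and 0.0249 without pre-secretory A and C), CRC (3.04, SE 2.02, adjusted p = 0.461), MYB21 (1.15, SE 1.17, adjusted p = 0.618), MYB24 (2.28, SE 1.81, adjusted p = 0.526), SPS1F (-0.08, SE 0.57, adjusted p = 0.958) and BCA1 (0.15, SE 2.14, adjusted p = 0.981) also missed the test. Outside the lists AT5G41080 fell by 3.95 (SE 0.51, adjusted p = 0.00272, or 0.364 without secretory B).

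In total 21 loci passed for procumbens secretory against pre-secretory nectary (2 higher, 19 lower, 9.52% higher), and 376 after rescaling (40.7% higher). The count was 965 without pre-secretory A, 2, 248 and 1 without pre-secretory B, C and D, and 2 and 0 without secretory A and B (limma, 2069 loci at an unadjusted p under 0.05 with all libraries). The 20-library fit called 4652 loci (2264 higher, 2388 lower), all 21 among them in the same direction. There PSY rose by 3.73 (SE 0.66, adjusted p = 0.00133), BAM1 rose by 2.94 (SE 0.54, adjusted p = 0.00155) and AT4G20860 rose by 4.01 (SE 1.27, adjusted p = 0.0238). Cell cycle genes counted 6 lower of 8, the same adjusted over the list alone, camera adjusted p = 0.00608, adjusted p = 0.837 with an estimated correlation. The mitotic cyclin CYCB1;1 fell by 2.62 (SE 0.54, adjusted p = 0.0026). Senescence and chlorophyll breakdown genes counted 5 higher of 7, 6 higher adjusted over the list alone, camera adjusted p = 0.00608, adjusted p = 0.837 with an estimated correlation. The chlorophyll b reductase NYC1 rose by 1.94 (SE 0.35, adjusted p = 0.00145). SWEET9 (1.84, SE 0.81, adjusted p = 0.0897) and CRC (1.12, SE 0.43, adjusted p = 0.0543) missed the test there.

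Across 13080 loci the changes from pre-secretory to secretory nectary in the 2 species, which share no library, had a Pearson r of 0.47 and a Spearman r of 0.46, over loci that are not independent of one another. With all libraries 6 loci fell in both species (0.212 by chance) and 0 rose in both (0.0124 by chance, limma, with 2362 loci in herrerae and 2069 in procumbens at an unadjusted p under 0.05). These chance counts take calls in the 2 species as independent, but 1 variance per locus serves both, so they can be too low. The 20-library fit had 848 loci that rose in both (349 by chance), 875 that fell in both (432 by chance) and 182 in opposite directions. PSY and BAM1 rose in both there. The species difference in the PSY change was 0.98 (SE 1.03, adjusted p = 0.894) with all libraries and 0.71 (SE 0.88, adjusted p = 0.625) with 20, short of the test.

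At the end of secretion in herrerae PSY, P5CR, MYB21 and SHP2 fell and LOX2 and LOX3 rose (n = 3 and 3). The carotenoid, nectary development and jasmonate lists had camera calls at the preset correlation and none at an estimated one. PSY fell by 3.82 (SE 0.7, adjusted p = 0.000873), to 34.3 ± 8.15 TPM. The carotene hydroxylase BCH1 fell by 3.97 (SE 0.75, adjusted p = 0.00103), and the lycopene cyclase LCYB fell by 2.66 (SE 0.62, adjusted p = 0.00393). LCYE, the cyclase of the lutein branch, rose by 4.16 (SE 0.99, adjusted p = 0.00434). P5CR fell by 3.77 (SE 0.62, adjusted p = 0.000377), from 361 ± 19.9 to 26.7 ± 10 TPM. ProDH2, which breaks proline down, rose by 2.75 (SE 0.42, adjusted p = 0.00025). MYB21 fell by 4.67 (SE 1.1, adjusted p = 0.00399), and the MADS box factor SHP2 fell by 2.95 (SE 0.42, adjusted p = 0.000151). Of the lipoxygenases of jasmonate synthesis, LOX2 rose by 4.8 (SE 0.84, adjusted p = 0.000593), from 17.7 ± 8.51 to 481 ± 61.2 TPM, and LOX3 rose by 4.5 (SE 0.98, adjusted p = 0.00248). These calls held when any 1 of the 6 libraries was left out.

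Of the starch genes in herrerae after secretion, the plastid starch phosphorylase PHS1 rose by 4.3 (SE 0.58, adjusted p = 0.000105), SS2 rose by 4.63 (SE 0.62, adjusted p = 0.000108), and APS1, a subunit of ADP-glucose pyrophosphorylase, rose by 3.34 (SE 0.51, adjusted p = 0.00025). The starch lists had no camera call, and 4400 of all 13080 loci passed as higher in this comparison. PIP1;3 fell by 2.16 (SE 0.43, adjusted p = 0.00143). CDKB1;1, a cell cycle kinase, was listed at 0 in the secretory libraries and at 22.7 ± 3.51 TPM after secretion, and CDKB2;1 rose by 2.96 (SE 0.45, adjusted p = 0.00023). PSBP1 rose by 5.34 (SE 1.28, adjusted p = 0.00455). SWEET11 fell by 2.7 (SE 0.97, adjusted p = 0.0368, or 0.0739, 0.11 and 0.0585 without secretory A, B and C and 0.123 and 0.119 without post-secretory A and B), from 5852 ± 2550 to 1133 ± 1096 TPM. Each SE here also carries the spread of the procumbens libraries. SWEET9 (-4.02, SE 1.88, adjusted p = 0.0988) went from 10330 ± 2004 TPM (8289 to 12296) to 659 ± 235 TPM (396 to 850) and missed the test. So did CRC (-3.02, SE 1.9, adjusted p = 0.222), MYB24 (-3.06, SE 1.7, adjusted p = 0.165), SPS1F (-0.97, SE 0.54, adjusted p = 0.161), CWINV4 (-0.89, SE 2.28, adjusted p = 0.808), BCA1 (1.13, SE 2.01, adjusted p = 0.704) and AT4G20860 (0.51, SE 1.84, adjusted p = 0.876). Outside the lists AT3G12145 rose by 6.81 (SE 1.24, adjusted p = 0.000787) and AT1G52690 fell by 5.77 (SE 0.5, adjusted p = 1.19e-06).

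For herrerae post-secretory against secretory nectary 4659 loci passed (4400 higher, 259 lower, 94.4% higher), and 4220 after rescaling (54% higher). Of the 4659, 2523 stayed called in the same direction after rescaling. The count was 2642 without secretory C, and 2901 and 2806 without post-secretory B and C. Carotenoid genes counted 1 higher and 4 lower of 8, 1 higher and 5 lower adjusted over the list alone, camera adjusted p = 1.74e-06, adjusted p = 0.0641 with an estimated correlation. The nectary development list counted 2 lower of 6, the same adjusted over the list alone, camera adjusted p = 9.93e-07, adjusted p = 0.0641 with an estimated correlation. Jasmonate genes counted 6 higher of 7, the same adjusted over the list alone, camera adjusted p = 0.0469, adjusted p = 0.507 with an estimated correlation. Cell cycle genes counted 6 higher of 8, 7 higher adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.507 with an estimated correlation. Photosynthesis genes counted 9 higher of 13, 10 higher adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.679 with an estimated correlation. The sucrose synthesis and export genes had 1 lower of 8 (SWEET11) and a camera adjusted p = 0.00045, adjusted p = 0.0896 with an estimated correlation, but 0.0562 after rescaling. Without a camera call, starch synthesis genes counted 3 higher of 7, starch breakdown 3 higher and 1 lower of 9, monolignol 7 higher and 2 lower of 16, flavonoid 3 higher and 1 lower of 7 and auxin genes 3 higher of 7. Proline genes counted 1 higher and 1 lower of 7, ethylene 1 higher of 6, senescence 1 higher of 7, pump and aquaporin genes 1 higher and 1 lower of 8, and the trichome list 1 higher of 1. Those 10 counts were the same adjusted over each list alone. Some markers of other tissues also moved in the listed TPM. ANT (carpel and ovule) stood at 0 TPM during and 13.7 ± 6.51 TPM after secretion, and STK at 54.3 ± 13.6 and 101 ± 16.8 TPM. SUC2 (vascular) stood at 3.67 ± 0.577 and 16.7 ± 0.577 TPM, and the petal marker PI went the other way, from 15 ± 10.4 to 3.67 ± 2.08 TPM. The other petal marker, AP3, stood at 32 ± 8.19 and 31.3 ± 9.24 TPM. These values are not rescaled, and the median log2 change of all loci was 0.86 in this comparison. A change in the tissue dissected was not tested.

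Without the 3 procumbens libraries and with rescaling, 7637 loci passed for the end of secretion in herrerae (4307 higher, 3330 lower), 3938 of the 4659 among them in the same direction. There SWEET9 fell by 4.93 (SE 0.73, adjusted p = 4.1e-05), CRC fell by 3.92 (SE 0.39, adjusted p = 1.36e-06) and MYB24 fell by 3.96 (SE 0.6, adjusted p = 5.09e-05). Nectary development genes counted 6 lower of 6, the same adjusted over the list alone, camera adjusted p = 7.13e-05, adjusted p = 0.0531 with an estimated correlation.

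In procumbens, SWEET9, CRC and single carotenoid and jasmonate genes passed the test over all loci after secretion in the 20-library fit (n = 2 and 2). With all libraries 0 loci passed it (limma, 1189 at an unadjusted p under 0.05), and list tests made some calls, given below. In the 20-library fit SWEET9 fell by 4.64 (SE 0.89, adjusted p = 0.00098), from 32480 ± 5565 to 2231 ± 2015 TPM, CRC fell by 3.5 (SE 0.47, adjusted p = 8.01e-05), MYB24 fell by 4.37 (SE 0.73, adjusted p = 0.000381) and MYB21 fell by 3.58 (SE 0.46, adjusted p = 5.76e-05). BCH1 fell by 2.68 (SE 0.57, adjusted p = 0.00202), and LCYE rose by 2.77 (SE 0.64, adjusted p = 0.00336). LOX2 rose by 3.13 (SE 0.52, adjusted p = 0.000389), LOX3 rose by 4.19 (SE 0.58, adjusted p = 9.19e-05) and the allene oxide synthase AOS rose by 4.49 (SE 0.68, adjusted p = 0.000189). AT4G20860 fell by 4.63 (SE 1.39, adjusted p = 0.0162), and PHS1 rose by 2 (SE 0.32, adjusted p = 0.000312). Nectary development genes counted 5 lower of 6, the same adjusted over the list alone, camera adjusted p = 0.000881, adjusted p = 0.153 with an estimated correlation. Carotenoid genes counted 1 higher and 7 lower of 8, the same adjusted over the list alone, camera adjusted p = 0.00249, adjusted p = 0.552 with an estimated correlation. Jasmonate genes counted 6 higher of 7, the same adjusted over the list alone, camera adjusted p = 0.000881, adjusted p = 0.212 with an estimated correlation.

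With all 3 post-secretory libraries 0 loci passed in limma for procumbens post-secretory against secretory nectary (1189 at an unadjusted p under 0.05), 0 after rescaling (1611 at an unadjusted p under 0.05) and 1342 without post-secretory A. SWEET9 stood at 42648 TPM in post-secretory A and at 806 and 3656 in the other 2 libraries (-2.69, SE 2.1, adjusted p = 0.752). With all libraries MYB21 (-2.38, SE 1.23, adjusted p = 0.575, or 0.0482 without post-secretory A), CRC (-2.13, SE 2.13, adjusted p = 0.817), MYB24 (-2.68, SE 1.9, adjusted p = 0.725) and SPS1F (-0.62, SE 0.6, adjusted p = 0.807) missed the test. So did CWINV4 (-2.81, SE 2.55, adjusted p = 0.796), BCA1 (2.89, SE 2.25, adjusted p = 0.751) and AT4G20860 (-2.69, SE 2.06, adjusted p = 0.749). Jasmonate genes counted 0 of 7, 4 higher adjusted over the list alone, camera adjusted p = 0.00248, adjusted p = 0.398 with an estimated correlation. Carotenoid genes had a camera adjusted p = 0.00033, adjusted p = 0.385 with an estimated correlation, and nectary development genes 0.00633, adjusted p = 0.398 with an estimated correlation, but 0.146 after rescaling. The berberine bridge enzyme-like genes had 0.0489, adjusted p = 0.398 with an estimated correlation, but 0.228 after rescaling and 0.106 in the 20-library fit. The 20-library fit called 5003 loci (2799 higher, 2204 lower).

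For the start of secretion 3 loci passed the test of a difference between the species. AT1G52690 (5.98, SE 0.73, adjusted p = 0.00112) stood at 322 to 856 TPM in herrerae secretory nectaries and at 0 in every procumbens library. Its value is thus the herrerae change alone, and a locus missed in the matching of procumbens reads would give the same. That call held when any 1 of the 12 libraries was left out. AT5G62520, at 0 in every procumbens library but pre-secretory A (2 TPM), has the same limit. It (3.86, SE 0.61, adjusted p = 0.0273) lost its call in 6 of the 12, at 0.0815 to 0.338. AT4G38250 (3.89, SE 0.66, adjusted p = 0.0451) lost it in 11 of the 12, at 0.0745 to 0.599. These were the 3 loci called, with 867 at an unadjusted p under 0.05 and 64 called after rescaling (76.6% higher). The count was 1 without herrerae pre-secretory A or C or secretory B, 1 without procumbens secretory A or B, and 37 without procumbens pre-secretory A. Of 509 calls without the 3 libraries 37.7% were higher, and of 6 with a pseudocount of 0.1, 1 was. In the 20-library fit 1739 passed (49.3% higher), among them P5CR (3.29, SE 0.5, adjusted p = 0.0012), PIP1;3 (2.39, SE 0.46, adjusted p = 0.00475) and LOX2 (-2.03, SE 0.64, adjusted p = 0.0483). With all libraries P5CR (2.24, SE 0.9, adjusted p = 0.681, or 0.00324 without procumbens pre-secretory A), PIP1;3 (1.9, SE 0.63, adjusted p = 0.52), SWEET9 (-1.93, SE 2.74, adjusted p = 0.92), CRC (-0.99, SE 2.77, adjusted p = 0.969), CWINV4 (-5.75, SE 3.33, adjusted p = 0.8) and SPS1F (-0.13, SE 0.78, adjusted p = 0.986) missed the test. So did MYB21 (-1.21, SE 1.6, adjusted p = 0.912), MYB24 (-2.95, SE 2.48, adjusted p = 0.864), BCA1 (-0.66, SE 2.93, adjusted p = 0.985) and AT4G20860 (-4.25, SE 2.69, adjusted p = 0.817).

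From secretory to post-secretory nectary the single genes P5CR, ProDH2, SHP2, CDKB1;1 and CDKB2;1 passed the test of a difference between the species. ProDH2, SHP2 and CDKB1;1 were listed at 0 in procumbens at both stages. Their values are thus the herrerae change alone, and loci missed in the matching would give the same. CDKB2;1, at 0 to 1 TPM in procumbens secretory nectary and at 0 after secretion, has nearly the same limit. CDKB1;1 (4.55, SE 0.63, adjusted p = 0.00131) appeared after secretion in herrerae. Its call held when any 1 library was left out, with adjusted p between 0.00308 and 0.02. P5CR (-4.02, SE 0.93, adjusted p = 0.0453) fell in herrerae and stood at 17.5 ± 0.707 and 21 ± 1 TPM in procumbens. It lost its call without each of the 11 libraries in turn, at 0.0601 to 0.244. ProDH2 (2.75, SE 0.63, adjusted p = 0.0453) lost its call without each of the 11, at 0.0571 to 0.241. SHP2 (-2.95, SE 0.62, adjusted p = 0.0337) and CDKB2;1 (3.46, SE 0.67, adjusted p = 0.0204) lost theirs in 9 of 11, at 0.0518 to 0.201 and 0.0504 to 0.204. With rescaling P5CR differed by -4.71 (adjusted p = 0.00681) and in the 20-library fit by -4.54 (SE 0.53, adjusted p = 7.64e-05). PSY (-2.1, SE 1.06, adjusted p = 0.386), LOX2 (2.52, SE 1.25, adjusted p = 0.379) and SWEET11 (-3.72, SE 1.45, adjusted p = 0.258) missed the test. So did SWEET9 (-1.34, SE 2.82, adjusted p = 0.85), CRC (-0.89, SE 2.85, adjusted p = 0.908), CWINV4 (1.92, SE 3.42, adjusted p = 0.818) and SPS1F (-0.35, SE 0.81, adjusted p = 0.864). MYB21 (-2.29, SE 1.65, adjusted p = 0.538), MYB24 (-0.38, SE 2.55, adjusted p = 0.955), BCA1 (-1.76, SE 3.02, adjusted p = 0.811) and AT4G20860 (3.19, SE 2.77, adjusted p = 0.616) missed it as well.

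In all 97 loci passed for that difference (80 higher in herrerae, 17 lower, 82.5% higher), 243 after rescaling (39.1% higher) and 2727 in the 20-library fit (47.9% higher). The count was 26, 37 and 33 without herrerae secretory A, B and C, and 35, 23 and 19 without herrerae post-secretory A, B and C. It was 13 without procumbens secretory A or B, and 29 without procumbens post-secretory B. Nectary development genes counted 1 lower of 6, the same adjusted over the list alone, camera adjusted p = 0.00417, adjusted p = 0.307 with an estimated correlation, but 0.0585 after rescaling, 0.186 without the 3 libraries and 0.177 in the 20-library fit. Cell cycle genes counted 2 higher of 8, the same adjusted over the list alone, camera adjusted p = 0.00843, adjusted p = 0.307 with an estimated correlation. The sucrose, carotenoid and ethylene lists had camera calls with no called member, each with an adjusted p = 0.307 with an estimated correlation. The sucrose list had 0.0435, but 0.305 after rescaling, 0.53 without the 3 libraries and 0.802 in the 20-library fit. The carotenoid list had 0.0182, but 0.185 after rescaling, 0.53 without the 3 libraries and 0.641 in the 20-library fit. The ethylene list had 0.011, but 0.14 in the 20-library fit.

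Herrerae nectaries (n = 9 over 3 stages) had less photosynthesis and carbonic anhydrase transcript than leaves (n = 2) and more of a sucrose synthesis and a proline synthesis gene. RBCS1A (-7.82, SE 2.31, adjusted p = 0.0348, or 0.0511 without pre-secretory B, 0.0523 and 0.0505 without secretory A and C, 0.0557 and 0.0513 without post-secretory A and C and 0.222 and 0.309 without leaf A and B), at 71220 ± 21390 TPM in leaf, and BCA1 (-6.72, SE 1.93, adjusted p = 0.0307, or 0.0507 without post-secretory A and 0.237 and 0.263 without leaf A and B) were lower in nectary. SPS1F was 2.24 higher (SE 0.51, adjusted p = 0.0102, or 0.18 and 0.104 without leaf A and B) in nectary, and P5CR was 3.28 higher (SE 0.59, adjusted p = 0.00231, or 0.0603 and 0.0796 without leaf A and B). The cytosolic starch phosphorylase PHS2 (-2.31, SE 0.37, adjusted p = 0.000894, or 0.0577 without leaf B) and the anthocyanidin synthase LDOX (-3.26, SE 0.5, adjusted p = 0.000568, or 0.0732 without leaf A) were lower. SHP2 was 1.86 higher (SE 0.4, adjusted p = 0.00709, or 0.12 and 0.13 without leaf A and B). SWEET9 (3.36, SE 1.8, adjusted p = 0.272), CRC (2.9, SE 1.82, adjusted p = 0.367), MYB21 (2.97, SE 1.05, adjusted p = 0.0778), MYB24 (4.44, SE 1.63, adjusted p = 0.0893), CWINV4 (3.19, SE 2.18, adjusted p = 0.416) and AT4G20860 (-0.32, SE 1.77, adjusted p = 0.963) missed the test. Outside the lists AT1G02920 was higher by 4.5 (SE 0.67, adjusted p = 0.000442).

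Among lists, photosynthesis genes in herrerae nectary against leaf counted 12 lower of 13, 13 lower adjusted over the list alone, camera adjusted p = 1.27e-08, adjusted p = 0.333 with an estimated correlation. Carbonic anhydrases counted 3 lower of 4, the same adjusted over the list alone. Flavonoid genes counted 3 lower of 7, 4 lower adjusted over the list alone, camera adjusted p = 0.004, adjusted p = 0.333 with an estimated correlation. Nectary development genes counted 1 higher of 6, 4 higher adjusted over the list alone, camera adjusted p = 0.00222, adjusted p = 0.333 with an estimated correlation. Starch breakdown genes counted 2 lower of 9, 3 lower adjusted over the list alone, camera adjusted p = 0.0243, adjusted p = 0.333 with an estimated correlation, but 0.0738 without the 3 libraries. Markers of other tissues counted 2 lower of 3, the same adjusted over the list alone (vascular), 1 higher of 2, 2 higher adjusted over the list alone (petal), 1 higher and 1 lower of 4, 1 higher and 2 lower adjusted over the list alone (carpel and ovule) and 1 lower of 3, 1 higher and 1 lower adjusted over the list alone (pollen and anther). The number of loci called was 1412 (189 higher, 1223 lower, 13.4% higher), 2587 after rescaling (30% higher). With the 3 dominant loci removed it was 3707, and the direction turned (2672 higher, 1035 lower, 72.1% higher). Those loci were picked in herrerae nectaries, and loci high in leaf stayed in. Their removal thus raises other nectary values against leaf by construction (median log2 change from 0.04 to 0.47). The count was 94 and 118 without leaf A and leaf B. In the 20-library fit 6045 passed (2474 higher, 3571 lower), all 1412 among them in the same direction. There SWEET9 (3.27, SE 0.69, adjusted p = 0.0012), CRC (2.82, SE 0.37, adjusted p = 1.5e-05) and MYB24 (4.38, SE 0.57, adjusted p = 1.44e-05) were higher than in leaf. Nectary development genes counted 6 higher of 6, the same adjusted over the list alone, camera adjusted p = 3.17e-05, adjusted p = 0.0426 with an estimated correlation, a call under both correlations.

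Procumbens nectaries (n = 9) differed from leaves (n = 3) in SWEET9, LOX2 and the anthocyanin gene DFR, and leaf A held nectary transcripts: 7042 TPM of SWEET9 against 28 and 11 in leaf B and C. SWEET9 was 6 higher (SE 1.55, adjusted p = 0.0472, or 0.0635 and 0.0686 without pre-secretory B and C, 0.104 and 0.0926 without secretory A and B, 0.067 without post-secretory A and 0.559 and 0.375 without leaf B and C) in nectary. LOX2 (-2.95, SE 0.69, adjusted p = 0.04, or 0.0567 and 0.0619 without pre-secretory B and C, 0.101 and 0.0864 without secretory A and B and 0.559 and 0.366 without leaf B and C) and the dihydroflavonol reductase DFR (-2.56, SE 0.62, adjusted p = 0.0424, or 0.056 and 0.0648 without pre-secretory B and C, 0.101 and 0.0864 without secretory A and B, 0.062 without post-secretory A and 0.559 and 0.366 without leaf B and C) were lower. CRC (4.39, SE 1.57, adjusted p = 0.0893, or 0.00668 without pre-secretory A and 0.00231 without leaf A), MYB24 (4.58, SE 1.4, adjusted p = 0.0622, or 0.007 without pre-secretory A, 0.0394 without post-secretory C and 0.00108 without leaf A), SPS1F (1.47, SE 0.44, adjusted p = 0.0595, or 0.0198 without pre-secretory A, 0.0412 without post-secretory C and 0.00149 without leaf A) and BCA1 (-4.52, SE 1.66, adjusted p = 0.0952, or 0.0065 without pre-secretory A and 0.0203 without leaf A) missed the test with all libraries. So did CWINV4 (2.45, SE 1.88, adjusted p = 0.407), MYB21 (1.91, SE 0.91, adjusted p = 0.173, or 0.0355 without pre-secretory A and 0.0223 without leaf A) and AT4G20860 (4.76, SE 1.52, adjusted p = 0.0678, or 0.0274 without pre-secretory A, 0.0449 without post-secretory C and 0.000341 without leaf A). In the 20-library fit (n = 7 and 2) SWEET9 (8.17, SE 0.72, adjusted p = 2.05e-07), CRC (6.7, SE 0.38, adjusted p = 3.9e-09), MYB24 (6.43, SE 0.59, adjusted p = 3.26e-07) and AT4G20860 (6.75, SE 1.12, adjusted p = 0.00013) were higher in nectary. RBCS1A (-9.57, SE 1.33, adjusted p = 2.47e-05) and BCA1 (-7.05, SE 1.27, adjusted p = 0.000266) were lower.

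The procumbens nectary against leaf test called 370 loci (55 higher, 315 lower, 14.9% higher), 1777 after rescaling (30.1% higher) and 6894 with 20 libraries (46.2% higher), all 370 among them in the same direction. Without the 3 libraries alone 7593 passed, and most were higher (5356 higher, 2237 lower, 70.5% higher). The count was 3263, 60 and 7 without pre-secretory A, B and C, and 1 without secretory A or B. It was 77 and 965 without post-secretory A and C, and 4651, 1 and 1 without leaf A, B and C. Photosynthesis genes counted 0 of 13, 12 lower adjusted over the list alone, camera adjusted p = 2.93e-07, adjusted p = 0.489 with an estimated correlation. With 20 libraries they counted 13 lower of 13, the same adjusted over the list alone, camera adjusted p = 8.92e-08, adjusted p = 0.515 with an estimated correlation. Nectary development genes counted 0 of 6, 3 higher adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.489 with an estimated correlation. With 20 libraries these counted 5 higher of 6, the same adjusted over the list alone, camera adjusted p = 0.000535, adjusted p = 0.109 with an estimated correlation. Cell cycle genes counted 0 of 8, 2 lower adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.489 with an estimated correlation. Flavonoid genes counted 1 lower of 7, the same adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.489 with an estimated correlation, but 0.062 after rescaling.

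For the species difference in nectary against leaf, P5CR (3.31, SE 0.78, adjusted p = 0.0692, or 8.52e-05 and 0.0432 without procumbens pre-secretory A and D and 0.0463 without procumbens leaf A), LOX2 (2.93, SE 1.06, adjusted p = 0.316), SWEET9 (-2.64, SE 2.37, adjusted p = 0.817) and CRC (-1.49, SE 2.4, adjusted p = 0.91) missed the test with all libraries. So did CWINV4 (0.74, SE 2.88, adjusted p = 0.972), SPS1F (0.76, SE 0.68, adjusted p = 0.815), MYB21 (1.05, SE 1.39, adjusted p = 0.89), MYB24 (-0.15, SE 2.15, adjusted p = 0.992), BCA1 (-2.19, SE 2.54, adjusted p = 0.868) and AT4G20860 (-5.09, SE 2.33, adjusted p = 0.52, or 0.019 without procumbens leaf A). In the 20-library fit P5CR (3.5, SE 0.46, adjusted p = 0.000116) and LOX2 (3.86, SE 0.59, adjusted p = 0.000385) were higher in herrerae. SWEET9 (-4.9, SE 1, adjusted p = 0.00299), CRC (-3.88, SE 0.53, adjusted p = 0.000159) and AT4G20860 (-7.16, SE 1.56, adjusted p = 0.00449) were lower. Proline genes counted 0 of 7, 3 higher adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.22 with an estimated correlation, but 0.0947 after rescaling, 0.0989 without the 3 libraries and 0.572 in the 20-library fit. The cell cycle list had a camera adjusted p = 0.0122, adjusted p = 0.76 with an estimated correlation, but 0.0947 after rescaling. 54 loci passed (20 higher, 34 lower), 158 after rescaling (43% higher) and 3349 with 20 libraries (47.7% higher). With the 3 dominant loci removed 130 passed, and the direction turned (102 higher, 28 lower). That removal raises herrerae nectary values here too by construction (median log2 difference from -0.18 to 0.35). The count was 2 and 7 without herrerae leaf A and B, and 325 without procumbens pre-secretory A. It was 35 and 34 without procumbens secretory A and B, 83 without procumbens post-secretory A, and 461, 18 and 29 without procumbens leaf A, B and C.

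Secretory nectaries of herrerae (n = 3) had higher listed values of a sucrose exporter and a proline enzyme than those of procumbens (n = 2), and lower ones of 4CL1 and PAL1. The matching of each species' reads to the loci is not known. Matching and a difference between species are thus not separated, here and in the other comparisons of herrerae with procumbens below. SWEET11 was 7.59 higher (SE 1.08, adjusted p = 0.000117), at 5852 ± 2550 against 28.5 ± 10.6 TPM. P5CR was 4.29 higher (SE 0.69, adjusted p = 0.000322), at 361 ± 19.9 against 17.5 ± 0.707 TPM. The ligase 4CL1 (-5.19, SE 0.84, adjusted p = 0.000333) and the ammonia lyase PAL1 (-2.94, SE 0.47, adjusted p = 0.00032) of phenylpropanoid synthesis and the aquaporin PIP1;1 (-4.07, SE 0.68, adjusted p = 0.000433) were lower. These 5 calls held when any 1 of the 5 libraries was left out. SHP2 and ProDH2 were listed at 0 in procumbens, and the berberine bridge enzyme-like AT1G30700 was listed at 0 in herrerae. SWEET9 (-1.66, SE 2.1, adjusted p = 0.569), CWINV4 (-5.05, SE 2.55, adjusted p = 0.132), AT4G20860 (-5.12, SE 2.06, adjusted p = 0.0623), CRC (0.02, SE 2.13, adjusted p = 1), SPS1F (1.36, SE 0.6, adjusted p = 0.0869), MYB21 (0.81, SE 1.23, adjusted p = 0.644), MYB24 (-0.65, SE 1.9, adjusted p = 0.825) and BCA1 (-0.99, SE 2.25, adjusted p = 0.765) missed the test. Outside the lists AT5G50290 (12.49, SE 1.54, adjusted p = 3.36e-05) and AT5G44360 (-10.58, SE 2.42, adjusted p = 0.00354) had among the highest and lowest values.

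Monolignol genes in herrerae against procumbens secretory nectary counted 8 lower of 16, 10 lower adjusted over the list alone, no camera call (adjusted p = 0.125), and 1 higher and 5 lower after rescaling. Starch synthesis genes counted 3 lower of 7, 1 higher and 3 lower adjusted over the list alone, no camera call (adjusted p = 0.952), and 1 higher and 1 lower after rescaling. Starch breakdown genes counted 3 lower of 9, the same adjusted over the list alone, no camera call (adjusted p = 0.952), and 1 higher after rescaling. Auxin genes counted 3 lower of 7, 1 higher and 4 lower adjusted over the list alone, no camera call (adjusted p = 0.787), and 1 higher and 3 lower after rescaling. Pumps and aquaporins counted 3 lower of 8, the same adjusted over the list alone, no camera call (adjusted p = 0.952), and 1 higher and 1 lower after rescaling. Berberine bridge enzyme-like genes counted 1 lower of 6, 3 lower adjusted over the list alone, no camera call (adjusted p = 0.952), and 1 lower after rescaling. The number of loci called was 4269 (622 higher, 3647 lower, 14.6% higher), 3448 after rescaling (50.4% higher). Of the 4269, 2329 stayed called in the same direction after rescaling. The count was 2470, 1571 and 1440 without herrerae secretory C and procumbens secretory A and B. The 20-library fit called 6347, 3405 of the 4269 among them in the same direction. Of the 4269 loci, 461 were listed at 0 in every library of 1 species, the 3 procumbens libraries aside.

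Before secretion SWEET11 was higher and 4CL1 and PAL1 lower in herrerae as well (n = 3 and 4). SWEET11 was 4.83 higher (SE 0.91, adjusted p = 0.00156), at 2311 ± 1385 against 175 ± 282 TPM, and BCH1 3.73 higher (SE 0.7, adjusted p = 0.00157). 4CL1 (-4.95, SE 0.7, adjusted p = 0.000146), PAL1 (-2.15, SE 0.4, adjusted p = 0.00138) and PIP1;3 (-2.66, SE 0.4, adjusted p = 0.00026) were lower, and each of these 5 calls held when any 1 library was left out. SPS1F was 1.49 higher (SE 0.5, adjusted p = 0.0443, or 0.124 and 0.153 without herrerae pre-secretory B and C and 0.0675 and 0.12 without procumbens pre-secretory B and D). SWEET9 (0.27, SE 1.76, adjusted p = 0.922), CRC (1, SE 1.78, adjusted p = 0.698), CWINV4 (0.7, SE 2.13, adjusted p = 0.83) and MYB21 (2.02, SE 1.03, adjusted p = 0.162) missed the test. So did MYB24 (2.3, SE 1.59, adjusted p = 0.298), BCA1 (-0.33, SE 1.88, adjusted p = 0.911) and AT4G20860 (-0.87, SE 1.73, adjusted p = 0.732). Nectary development genes counted 1 higher of 6, the same adjusted over the list alone, camera adjusted p = 0.00403, adjusted p = 0.46 with an estimated correlation, but 0.14 after rescaling, 0.215 without the 3 libraries and 0.446 in the 20-library fit. Monolignol genes counted 6 lower of 16, the same adjusted over the list alone, no camera call (adjusted p = 0.122), and 5 lower after rescaling. The number of loci called was 2469 (565 higher, 1904 lower, 22.9% higher), 2531 after rescaling (53.1% higher) and 6334 with 20 libraries. Of the 2469, 1745 stayed called in the same direction after rescaling. With the 3 dominant loci removed 64.7% of 2153 calls were higher. CRC reversed without the 3 procumbens libraries (-1.16, SE 0.44, adjusted p = 0.0293) and missed the test in the 20-library fit (-0.32, SE 0.39, adjusted p = 0.522), where SWEET11 was 6.7 higher (SE 0.64, adjusted p = 4.2e-07) and 4CL1 (-4.73, SE 0.69, adjusted p = 3.81e-05) and PAL1 (-1.09, SE 0.21, adjusted p = 0.000602) lower. The count was 1144 and 1103 without herrerae pre-secretory A and C, and 5742, 1325, 1618 and 1330 without procumbens pre-secretory A, B, C and D.

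After secretion SWEET11 was again 3.86 higher (SE 0.97, adjusted p = 0.00719) in herrerae (n = 3 and 3), and PHS1 2.38 higher (SE 0.58, adjusted p = 0.0056). PIP1;1 (-3.97, SE 0.61, adjusted p = 0.000148), at 51 ± 9.64 against 832 ± 257 TPM, and PIP1;3 (-3.09, SE 0.43, adjusted p = 6.04e-05) were lower. The kinases CDKB1;1 and CDKB2;1 stood at 22.7 ± 3.51 and 14.7 ± 2.08 TPM in herrerae and were listed at 0 in procumbens. SWEET9 (-3, SE 1.88, adjusted p = 0.257), CRC (-0.87, SE 1.9, adjusted p = 0.768), CWINV4 (-3.13, SE 2.28, adjusted p = 0.331) and SPS1F (1.01, SE 0.54, adjusted p = 0.182) missed the test. So did MYB21 (-1.49, SE 1.1, adjusted p = 0.339), MYB24 (-1.03, SE 1.7, adjusted p = 0.69), BCA1 (-2.75, SE 2.01, adjusted p = 0.334) and AT4G20860 (-1.93, SE 1.84, adjusted p = 0.471). Cell cycle genes counted 2 higher of 8, the same adjusted over the list alone, camera adjusted p = 0.00598, adjusted p = 0.833 with an estimated correlation. The number of loci called was 3035 (1285 higher, 1750 lower, 42.3% higher), 4060 after rescaling (53.5% higher), 6098 with 20 libraries. With the 3 dominant loci removed 67.8% of 3375 calls were higher. The count was 2023 and 1798 without herrerae post-secretory A and B.

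Leaves shared part of the species differences (n = 2 and 3): PIP1;1 (-4.01, SE 0.68, adjusted p = 0.00108), at 32 ± 2.83 against 537 ± 120 TPM, was lower in herrerae, and its call held when any 1 library was left out. LOX2 (-3.37, SE 0.93, adjusted p = 0.0226, or 0.128 and 0.16 without herrerae leaf A and B and 0.0637 and 0.0724 without procumbens leaf B and C) was also lower. SWEET9 (1.18, SE 2.1, adjusted p = 0.746), CRC (1.54, SE 2.13, adjusted p = 0.669), CWINV4 (-3.23, SE 2.55, adjusted p = 0.444) and SPS1F (0.52, SE 0.6, adjusted p = 0.603) missed the test. So did MYB21 (-0.61, SE 1.23, adjusted p = 0.779), MYB24 (0.35, SE 1.9, adjusted p = 0.927), BCA1 (0.83, SE 2.25, adjusted p = 0.837) and AT4G20860 (2.45, SE 2.06, adjusted p = 0.473, or 0.0396 without procumbens leaf A). Photosynthesis genes had 1 higher of 13 and a camera adjusted p = 0.00944, adjusted p = 0.95 with an estimated correlation, but 0.293 after rescaling, 0.33 without the 3 libraries and 0.706 in the 20-library fit. The median of that list was 2.28 with all libraries and 0.54 without the 3. The number of loci called was 1460 (615 higher, 845 lower, 42.1% higher), 2260 after rescaling (52.9% higher), 5094 with 20 libraries. It was 428 and 446 without herrerae leaf A and B. Of the 1460 loci, 515 were listed at 0 in every library of 1 species, the 3 procumbens libraries aside.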

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

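The tests of explanations in this part were chosen after the results were seen, while the tests of species differences were planned. In the only group of 4 libraries, 12 sets of values were checked with Dixon's ratio for a library far from the others. Of these 2 passed, where chance passes about 1 in 20. Both were in procumbens pre-secretory A: BCA1 at 1966 TPM, and the share of AT5G50290, AT5G36210 and AT2G01021 at 1.08%. Planned tests of a difference between species called 3 loci for the start of secretion, 97 for its end and 54 for nectary against leaf. At the start these were AT1G52690 (5.98), AT5G62520 (3.86) and AT4G38250 (3.89), and at the end they included P5CR (-4.02), ProDH2 (2.75), SHP2 (-2.95), CDKB2;1 (3.46) and CDKB1;1 (4.55). AT1G52690, ProDH2, SHP2 and CDKB1;1 were listed at 0 in the procumbens libraries of their comparison, and AT5G62520 in all but pre-secretory A (2 TPM). CDKB2;1 was listed at 0 to 1 TPM in procumbens secretory nectary and at 0 after secretion. Matching and a difference between species are thus not separated for any of these loci.

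Procumbens pre-secretory A, post-secretory A and leaf A lie nearest another group, as pre-secretory C does by less, which was not tested further. Of 252 loci listed at 0 in all herrerae and above 0 in the other 9 procumbens libraries, 19 (7.54%) were above 0 in pre-secretory A, as were 225 of the 231 loci (97.4%) with the opposite pattern. Among procumbens-only loci of at least 10 TPM on average, 8 of 156 (5.13%) were above 0, which argues against a mixture with a large procumbens share. In leaf A, 0 of the 13 photosynthesis loci reached 0.5 of the mean of leaf B and C (0.159 to 10.5% of it), while 251 of 252 procumbens-only loci were above 0. Post-secretory A and leaf A, also not used to pick these loci, had 245 and 251 of the 252 above 0, and 0 and 3 of the 231. These values argue against the labelled species for pre-secretory A. Whether it is herrerae leaf, and whether leaf A holds nectary tissue in place of leaf, stay open, and no biological explanation was tested.

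In herrerae nectaries AT5G50290, AT5G36210 and AT2G01021 hold a large share of the signal, and the median of all loci moves by 0.86 from secretory to post-secretory nectary. With the 3 loci removed the median was 0.50 (0.49 to 0.54 leaving out each of the 6 libraries), which argues against their share as the whole cause and leaves it open as a part. The ratio of AT5G36210 to AT5G50290 stayed between 0.364 and 0.469 over herrerae libraries, and 0 of 765 other loci had as low a spread of the log2 ratio (0.119 against 0.33 for the lowest), so 1 RNA source behind them in herrerae could be the case. In procumbens the loci come apart, with AT5G36210 at 3555 to 34717 TPM and AT5G50290 at 4 to 56 TPM outside pre-secretory A, and AT2G01021 at 730 TPM in leaf A against 20960 of AT5G36210, so the ratio speaks for herrerae alone. A biological rise of that RNA in nectaries was not tested.

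P5CR, which makes proline, fell after secretion in herrerae and stood at 17.5 ± 0.707 and 21 ± 1 TPM in procumbens (difference -4.02, SE 0.93, adjusted p = 0.0453, 3 and 3 herrerae and 2 and 3 procumbens libraries). Scaling as the whole cause is argued against by -4.71 after rescaling, and the 3 procumbens libraries by -4.02 without them, with adjusted p between 2.83e-05 and 0.111 over the alternatives. Different matching of the reads of the 2 species to this locus cannot be told apart from a difference between species, since the herrerae fall (-3.77) is the pattern itself and no value tests the matching in procumbens. Whether the plants or the matching differ stays open, and the call ended without each of the 11 libraries in turn (0.0601 to 0.244).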

How the results depend on the processing

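All settings without 3 libraries and with 3 loci removed were chosen after the data were seen, and the others were planned. Leaving out single libraries aside, for the 13 counts of calls, the list calls and the correlation between species, 57 alternative values stayed within 1.5 times (0.05 for the correlation) and 75 moved further. Of 611 values of named genes, 4727 alternative values stayed on their side of the threshold, 677 passed it newly, 236 no longer passed it and 9 reversed with a call. Leaving out 1 library at a time, 51 values of the 13 counts of calls stayed and 64 moved, and for genes 4130 stayed, 126 passed newly and 530 no longer passed. Without the 3 procumbens libraries and without rescaling, log2 changes within herrerae stay as they were. Calls gained there within herrerae thus follow from the variance shared over groups and the adjustment. The cause of the other changes was not tested. Below, start, end and leaf contrast are secretory against pre-secretory, post-secretory against secretory and nectary against leaf.

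Counts of calls moved to 560 (herrerae start), 60 (procumbens start), 6 (procumbens end), 8 (procumbens leaf contrast) and 6 (start difference) with a pseudocount of 0.1, and to 235 (procumbens leaf contrast), 965 (species leaf), 1 (start difference) and 34 (leaf contrast difference) with a mean TPM of at least 5. No filter moved none past 1.5 times. Median ratio rescaling gave 1161 (herrerae start), 2587 (herrerae leaf contrast), 376 (procumbens start), 1777 (procumbens leaf contrast), 2260 (species leaf), 64 (start difference), 243 (end difference) and 158 (leaf contrast difference), with 17 list calls of 208 in place of 28. An estimated correlation gave 0 list calls (limma). A fit on the compared groups alone gave 816 (herrerae start), 7822 (herrerae end), 3818 (herrerae leaf contrast), 0 (procumbens start), 1 (procumbens leaf contrast), 176 (species pre-secretory), 7120 (species secretory), 1 (start difference) and 1206 (end difference) (limma, 2069 loci at an unadjusted p under 0.05 for the procumbens start with all groups). Removing the 3 loci gave 695 (herrerae start), 3707 (herrerae leaf contrast), 58 (procumbens start), 1183 (procumbens leaf contrast), 2582 (species secretory), 5 (start difference), 158 (end difference) and 130 (leaf contrast difference). Letters paired no libraries, with correlations of -0.109 to 0.181 in herrerae and -0.496 to 0.352 in procumbens between libraries of the same letter, and a block by letter gave 106 (herrerae start), 614 (herrerae leaf contrast), 1 (procumbens start), 1142 (species pre-secretory), 1 (start difference), 16 (end difference) and 33 (leaf contrast difference).

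Leaving out the 3 procumbens libraries gave 3309 (herrerae start), 7751 (herrerae end), 4141 (herrerae leaf contrast), 3121 (procumbens start), 3973 (procumbens end), 7593 (procumbens leaf contrast), 7682 (species pre-secretory), 7603 (species secretory), 6019 (species post-secretory), 3514 (species leaf), 509 (start difference), 1729 (end difference) and 2866 (leaf contrast difference). With rescaling as well it gave 4381 (herrerae start), 7637 (herrerae end), 6045 (herrerae leaf contrast), 4652 (procumbens start), 5003 (procumbens end), 6894 (procumbens leaf contrast), 6334 (species pre-secretory), 6098 (species post-secretory), 5094 (species leaf), 1739 (start difference), 2727 (end difference) and 3349 (leaf contrast difference), and with loci detected in both species 6917 (species pre-secretory), 6906 (species secretory), 5198 (species post-secretory), 2697 (species leaf), 391 (start difference), 1390 (end difference) and 2458 (leaf contrast difference). Leaving out 1 library at a time gave 52 to 235 (herrerae start), 2642 to 3852 (herrerae end), 94 to 1424 (herrerae leaf contrast), 0 to 965 (procumbens start), 0 to 1342 (procumbens end), 1 to 4651 (procumbens leaf contrast), 1103 to 5742 (species pre-secretory), 1440 to 3739 (species secretory), 1798 to 2864 (species post-secretory), 428 to 1417 (species leaf), 1 to 37 (start difference), 13 to 100 (end difference) and 2 to 461 (leaf contrast difference). The Pearson correlation of stage changes between the species lay between 0.437 and 0.504 over the settings it was computed for. These were all libraries, no 3 procumbens libraries with and without rescaling, a mean TPM of at least 5 and a pseudocount of 0.1.

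Reversed values, none called with all libraries, were ETR1 (AT1G66340, -0.53), DPE2 (AT2G40840, -0.74), C3H (AT2G40890, -0.54), AHA2 (AT4G30190, -0.67) and CTR1 (AT5G03730, -0.62) at the herrerae end, LOX2 (AT3G45140, 1.2) for species pre-secretory and ProT1 (AT2G39890, -0.90) in the end difference, all without the 3 libraries and with rescaling. CRC (AT1G69180) reversed for species pre-secretory to -1.16 without the 3 libraries, with or without the filter on both species. The cause was not tested for any of the 9. Depth limits cannot be given, since TPM keeps no read counts.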

Other observations

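The tests of other splits of the libraries in this part were chosen after the counts were seen. P5CR stood at 98 ± 42, 361 ± 19.9 and 26.7 ± 10 TPM before, during and after secretion in herrerae and at 9 ± 1.41 TPM in leaf. In procumbens it stood at 30.5 ± 19, 17.5 ± 0.707, 21 ± 1 and 20.7 ± 3.51 TPM. SHP1, a MADS box factor of the carpel, stood at 296 ± 91 TPM in herrerae and 755 ± 62.9 TPM in procumbens secretory nectary. Of the 6 tested nectary development genes, SHP1 among them, 0 were called lower in herrerae with all libraries and 0 in the 20-library fit. Without the 3 libraries alone, 2 of them were.

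Other splits of the same libraries were refitted where both groups have at least 3. For herrerae secretory against pre-secretory nectary 1 of 10 splits, the real one, called as many loci (227, highest other 0), for post-secretory against secretory 1 of 10 (4659, highest other 0), and for the species after secretion 1 of 10 (3035, highest other 0). With 10 splits these are too few for a share under 0.05. For the species before secretion 3 of 35 splits called as many as the real 2469, so this test does not exclude chance. The highest called 6074, with procumbens pre-secretory A placed with herrerae A and C, which points to a structure of the samples, and without that library the real count was 5742. For procumbens nectary against leaf 13 of 100 splits, drawn at random apart from the real one, called as many as the real 370, so chance is not excluded, and the highest called 6844, with pre-secretory A, leaf B and leaf C as leaf, a structure again.

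Post-secretory A of procumbens lies nearest the secretory group and leaf A nearest the post-secretory group, each 1 place earlier in the order of the labels, and pre-secretory A nearest herrerae leaf. Pre-secretory C, nearest the secretory group, is off in the other direction and such a shift leaves it unexplained. A shift of labels by 1 place could give this order. It would also leave 3 libraries in each of the groups that now have 2 (herrerae leaf, procumbens secretory) or 4 (procumbens pre-secretory), the number the labels plan, and leave 2 in procumbens leaf, which now has 3. The 7.54% of procumbens-only loci above 0 in pre-secretory A is what such a shift needs of that library, no test here separates it from other wrong labels, and it remains a hypothesis.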
